A study of Mus musculus with 4 samples.

How the data were processed

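Poly(A) RNA was sequenced from bone marrow LSK cells, the lineage-negative fraction that carries Sca-1 and c-Kit and holds haematopoietic stem and early progenitor cells, of Afg3l2 knockout mice and wild-type mice. The labels give 2 libraries per group, 4 in all, numbered 1 and 2 within each group. They name fresh isolation, a PBS wash, random-hexamer priming after poly(A) selection and single-end Illumina sequencing. They do not say whether the libraries come from separate animals, how the knockout was made, which exon it removes, or whether the reads kept their strand. The p-values therefore measure only the spread between libraries.

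Per the labels, the authors used STAR 2.7.10a and featureCounts 2.0.1 with the GRCm38.p6 genome build; the annotation release, trimming and counting settings are not stated. The deposited table holds, for 15255 genes, a normalized signal per library in CPM (reads scaled to an effective library size), which was found to be scaled by edgeR's TMM factors. Dividing each deposited column by its smallest step gave whole reads, with 100% of values within 0.01 of a whole number. The deposited table also holds, per the file headers, the authors' log2 fold change and average log2 CPM. Its likelihood ratio is a score deposited by the authors for the test of each gene. The p-values and adjusted p-values (FDR) beside it are also the authors' own. Further deposited sheets hold the authors' lists of higher and lower genes and DAVID enrichment tables, whose fold enrichment is the ratio of a term's share of the list to its share of the background, per the file headers. All 15255 genes passed edgeR's filterByExpr, so the authors' table had already lost genes with few reads.

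Before the data were examined, the groups, the comparison, 37 gene lists, the rule for naming genes and most alternatives were fixed. The planned edgeR test needed raw counts. Because the deposited values are normalized, the planned fallback became the test: limma 3.58.1 in R 4.3.3 on log2(CPM + 1), with a trend, robust variance moderation, no replicate block and a two-sided test. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all 15255 genes. Fold ratios are ratios of mean CPM, while log2 fold changes are from the fit with its pseudocount of 1 CPM, which shortens the log2 fold change of genes with few reads. Errors are SD over the 2 libraries of a group for CPM and SE for log2 fold changes. The fit leaves 2 residual degrees of freedom, and 1 with a replicate block.

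Gene lists were tested with camera, two-sided, at a preset inter-gene correlation of 0.01, adjusted over 36 lists with at least 5 genes tested. The list of Xist and Y-linked genes served to compare the sex of the libraries and entered no test. The camera test was repeated with an estimated correlation, and fry was run as a self-contained test. Counts within a list are given over all genes and adjusted over the list alone.

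The genes named in the text are Afg3l2 and Mmadhc, the gene in the series title. To these were added the 10 highest and 10 lowest log2 fold changes among called protein-coding genes with a mean of at least 1 CPM and non-overlapping groups, leaving out predicted genes and antigen receptor segments. Up to 4 members with the smallest p were added from each list that was called or held a called gene. Any other gene was chosen after its values were seen, and the text says so. Positions are from GENCODE M21 on GRCm38, chosen because its identifiers fit the table best: 15226 of the 15255 identifiers were found in it, 14806 of them with the same version, and 29 were not found.

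The deposited statistics were refitted as an edgeR 4.0.16 likelihood ratio test with the replicate number as a block. The refit differed from the deposited log2 fold changes by at most 3.63e-08 over all 15255 genes, so the authors treated the numbers as pairing the libraries. The labels do not state what a number shares. Xist was high and Ddx3y low in both libraries numbered 2, so the number coincided with sex-linked RNA. The main fit has no block and counts that difference as spread within a group. Over 13795 genes at 1 CPM or more, the deviations of same-numbered libraries from their group mean had a correlation across genes of 0.286, and 0.260 without Xist and Y-linked genes. Genes are not independent replicates. A blocked fit is given beside a result where it changes the call or moves a count by more than 1.5 times.

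The alternatives were median-of-ratios scaling, a stricter filter (at least 1 CPM in both libraries of a group and a mean of at least 20 reads, which left 13304 genes), a pseudocount of 0.1 CPM, minimum log2 fold changes of 0.5 and 1, DESeq2 1.42.0, limma-voom, an edgeR quasi-likelihood fit with a replicate block, and leaving out each library in turn. With a library left out, the lone library of that group is assumed to vary as the other group does. That lone library is also set against 2 libraries that differ in sex-linked RNA, so each such fit is unbalanced for it. The limma fit with a replicate block and the refit of the authors' test were added after seeing the data. So was the edgeR fit without a block, which is the test planned for raw counts, run on recovered reads. Reads recovered from the deposited values were the input to edgeR, DESeq2 and voom.

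The fits were tested on simulated data of 15255 genes with 2 libraries per group. The limma fit recovered 37% of 100 genes changed 2-fold and 71% of 100 genes changed 4-fold, with 29 calls among 15030 unchanged genes. With a replicate block it recovered 43% and 76%, with 52 calls among unchanged genes. Simulated libraries of the same number shared no effect, so the run does not show what a block gains or costs where they do. Beside 37 and 71 genes recovered, 29 false calls are a larger share than the adjusted p threshold is meant to allow. The same held with the block, with 52 false calls beside 43 and 76 genes recovered. The counts of called genes in the data may therefore also hold more false calls than that threshold states. Camera with the preset correlation called a simulated list of 25 genes shifted by 1 on the log2 scale (adjusted p = 6.35e-24) and 0 of 36 unchanged lists. With an estimated correlation the same shifted list had an adjusted p = 0.270. That version thus did not recover a true shift of this size with 4 libraries. The simulated genes varied independently of each other, so the run does not test the preset on lists whose genes move together. In the data the estimated correlation ranged from -0.07 for endothelial and stromal genes to 0.85 for neutrophil genes.

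Library depth, as reads assigned to the genes of the table, ranged from 16522338 to 17271936. Groups of 2 are too small for an outlier test, and no batch, date or lane is given in the labels.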

Results

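The data are RNA-seq profiles of mouse LSK cells, the bone marrow fraction rich in haematopoietic stem and progenitor cells. There were 2 wild-type and 2 Afg3l2 knockout libraries. Reads assigned to genes numbered 17222255 and 17271936 in wild-type replicates 1 and 2, and 16908812 and 16522338 in knockout replicates 1 and 2. Between 15187 and 15219 of the 15255 genes had reads in each library. Pearson correlations of log2 values across genes were 0.967 between the wild-type libraries, 0.980 between the knockout libraries, and 0.938 to 0.962 between groups. Xist, the RNA that silences an X chromosome in female cells, stood at 0.113 and 889 CPM in wild-type replicates 1 and 2 and at 15.7 and 1004 CPM in knockout replicates 1 and 2. The Y-linked gene Ddx3y stood at 83.4 and 5.04 CPM, and at 72.4 and 3.50 CPM. Replicates 1 and 2 thus differed in sex-linked RNA, in the same direction in both groups. Knockout replicate 1 held more Xist than wild-type replicate 1, and both libraries numbered 2 held some Ddx3y. The source of these reads was not tested. Of the Xist and Y-linked list, 0 of 5 measured genes passed by limma or edgeR, with 0 at an unadjusted p under 0.05.

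The comparison asks how loss of Afg3l2, a subunit of the m-AAA protease of the mitochondrial inner membrane, alters the RNA of these cells, and the series title places Mmadhc downstream of it. Afg3l2 RNA fell in the knockout but did not vanish. Wild-type cells held 82.8 ± 4.53 CPM and knockout cells 33.4 ± 4.66 CPM (SD, n = 2 libraries each), a ratio of 0.404. The log2 fold change was -1.29 ± 0.16 (SE), with a limma adjusted p = 0.0115. Mmadhc, which acts in the intracellular handling of cobalamin, stood at 74.5 ± 4.46 CPM in wild-type and 84.2 ± 4.07 CPM in knockout cells and did not pass (log2 fold change 0.18 ± 0.14, limma adjusted p = 0.515). These data measure RNA only, so a link between Afg3l2 and Mmadhc through protein or its function was not tested. Afg3l2 (ENSMUSG00000024527) lies on chromosome 18 of GRCm38 from 67404764 to 67449172, and Mmadhc (ENSMUSG00000026766) on chromosome 2 from 50279881 to 50296801; both are protein-coding. Without knockout replicate 1 the adjusted p of Afg3l2 was 0.0551, and without knockout replicate 2 it was 0.161, with log2 fold changes of -1.43 and -1.15. The deleted exon is not known from the labels, so the reads that remain were not assigned to intact or truncated RNA.

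**Figure D1:**
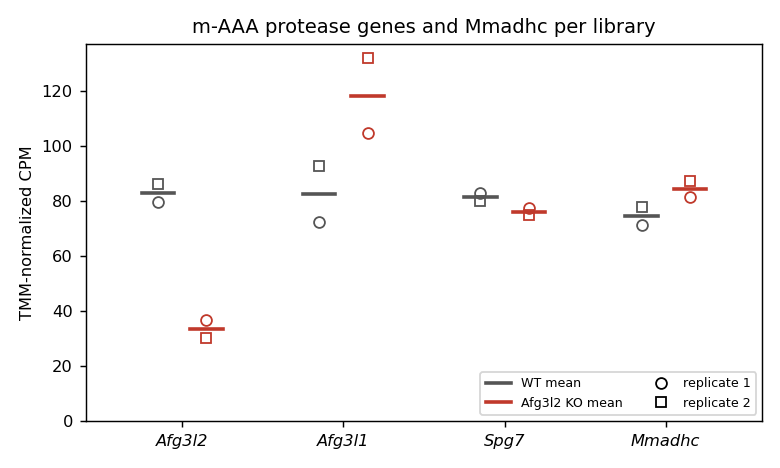
Normalized read counts (CPM, linear axis from 0) of Afg3l2, its m-AAA partners and Mmadhc in each library, with group means. Afg3l2 averages 82.8 CPM in wild-type and 33.4 CPM in knockout libraries, whereas Mmadhc averages 74.5 and 84.2 CPM.

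The 23 genes of the list on the m-AAA protease and mitochondrial quality control were not called as a group (limma camera adjusted p = 0.239, median log2 fold change 0.30). Of them 10 had an unadjusted p under 0.05, 7 higher and 3 lower, and 1 rose and 2 fell over all genes, with the same counts when adjusted over the list alone; with a replicate block 5 rose and 2 fell. Lonp1, a protease of the mitochondrial matrix, rose from 169 ± 14.9 to 350 ± 85.0 CPM (limma adjusted p = 0.0362). The other m-AAA subunit genes, Afg3l1 and Spg7, did not pass, with log2 fold changes of 0.52 and -0.10; Afg3l1 passed with a replicate block (adjusted p = 0.0275). Of 16 genes of cobalamin and propionate metabolism, 0 passed by limma over all genes, 0 adjusted over the list alone and 0 by edgeR. At an unadjusted p under 0.05 there were 5, and 4 passed with a replicate block; the list was not called (camera adjusted p = 0.133).

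Across the transcriptome, 369 of 15255 genes passed the limma test, 241 higher and 128 lower in the knockout. The highest included Trib3, a pseudokinase induced by amino acid shortage, which rose from 3.61 ± 0.858 to 135 ± 15.4 CPM, a ratio of 37.6 (log2 fold change 4.90 ± 0.21, adjusted p = 0.000353). Sfrp4, a secreted modulator of Wnt signalling, rose from 2.56 ± 0.495 to 69.0 ± 36.4 CPM, and Slc7a11, the cystine transporter subunit, from 1.29 ± 1.03 to 21.9 ± 1.01 CPM. Aldh1l2, an enzyme of mitochondrial folate metabolism, Etv4, P2rx3 and Gem also rose, with log2 fold changes of 3.95, 3.26, 3.34 and 3.19. Avil, which encodes the actin-binding protein advillin, rose from 0.235 ± 0.172 to 93.6 ± 60.3 CPM. The amino acid transporter Slc7a3 averaged 0.356 CPM in wild-type and 46.7 CPM in knockout cells, and the secreted glycoprotein Stc2 1.10 and 42.5 CPM; wild-type replicate 1 had no reads of either. Slc7a3 also passed DESeq2 and the authors' test but not edgeR (adjusted p = 0.0714), and Stc2 passed none of these 3 (adjusted p = 0.220, 0.156 and 0.219). Over the alternatives with all libraries, the adjusted p ranged from 1.86e-05 to 0.0790 for Slc7a3 and from 0.00108 to 0.330 for Stc2.

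Among the genes that fell, the chemokine Ccl9 dropped from 104 ± 13.5 to 12.7 ± 0.493 CPM, a ratio of 0.122 (log2 fold change -2.93 ± 0.17, adjusted p = 0.00152). The transcription factors Jun, Fos and Klf4 fell to ratios of 0.15, 0.154 and 0.175. Cx3cr1, the fractalkine receptor of monocytic cells, fell from 29.8 ± 5.87 to 5.27 ± 0.0257 CPM, and the lectin Clec10a from 28.3 ± 1.73 to 5.29 ± 1.85 CPM. Cd300lb, Bpifc and Drc7 fell to ratios of 0.0970, 0.0697 and 0.195. Siglech, a lectin of plasmacytoid dendritic cells, fell from 37.4 ± 18.6 to 4.02 ± 2.42 CPM, with an adjusted p = 0.0376 by limma and 0.0811 by edgeR. Trib3 (ENSMUSG00000032715) lies on chromosome 2 from 152337422 to 152344032, and Ccl9 (ENSMUSG00000019122) on chromosome 11 from 83572919 to 83578636. Avil (ENSMUSG00000025432) lies on chromosome 10 from 127000709 to 127020994 and shares exon sequence with Tsfm on the opposite strand, which reads of unknown strand do not tell apart. The same limit holds for Aldh1l2 (with D10Wsu102e), P2rx3 (Ssrp1) and Jun (Junos). Among called genes named from the lists it holds for Hk1 (Hk1os), Gclm (Gm17494), Cdkn1a (1700023B13Rik), Csf1r (Hmgxb3), Oasl1 (Gm13822) and mt-Nd6 (mt-Nd5).

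In all 369 called genes the groups did not overlap. The test selects for such separation, so this is no further support for the calls. The groups also did not overlap for 8253 of all 15255 genes. The number of genes called depended on single libraries: it was 656 without wild-type replicate 1, 1068 without wild-type replicate 2, 64 without knockout replicate 1 and 0 by limma without knockout replicate 2. For that last fit 1209 genes had an unadjusted p under 0.05, and edgeR called 3 genes, so no gene named here passed limma without knockout replicate 2. With the replicate number as a block, limma called 1779 genes, 1013 higher and 766 lower, of which 365 were among the 369 and changed the same way. EdgeR without a block, the test planned for raw counts, called 287 genes on recovered reads, 194 higher and 93 lower. All 287 were among the 369 and changed the same way. Limma-voom called 117 genes. Among the genes of highest and lowest fold change it did not call Avil (adjusted p = 0.136), Sfrp4, P2rx3, Slc7a3, Stc2, Bpifc, Siglech, Klf4 and Drc7. Of the called list genes named below it did not call Lonp1, mt-Nd6, Idh2, Hk1, Cdkn1a, Gdf15, Bbc3, Gclm, Oasl1, Ccl3, Tnfaip2, Samd14, F2r, Cd48, Notch1, Csf1r, Cma1, Nupr1 and Pecam1, with adjusted p-values of 0.0523 (Nupr1) to 0.0974 (Cma1).

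The list with the most called genes was that of targets of ATF4, the transcription factor of the integrated stress response. Of 35 measured genes in that list, 26 rose and 0 fell; adjusted over the list alone, 32 rose and 1 fell. The stress sensor Sesn2 rose from 10.04 ± 2.92 to 75.3 ± 19.2 CPM, a ratio of 7.5. The amino acid transporter Slc7a5 rose from 142 ± 25.9 to 534 ± 78.2 CPM, a ratio of 3.77. Asparagine synthetase Asns rose to a ratio of 8.11, the folate enzymes Mthfd2 and Shmt2 to 3.71 and 2.51, and the stress factor Ddit3 to 3.05; these 4 list members were chosen after their values were seen. Atf4 itself, also chosen so, did not pass, with a log2 fold change of 0.60 (adjusted p = 0.0663, and 0.0115 with a replicate block). The list's median log2 fold change was 1.44 and its camera adjusted p = 1.27e-30, against an adjusted p = 0.449 with an estimated correlation.

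**Figure D2:**
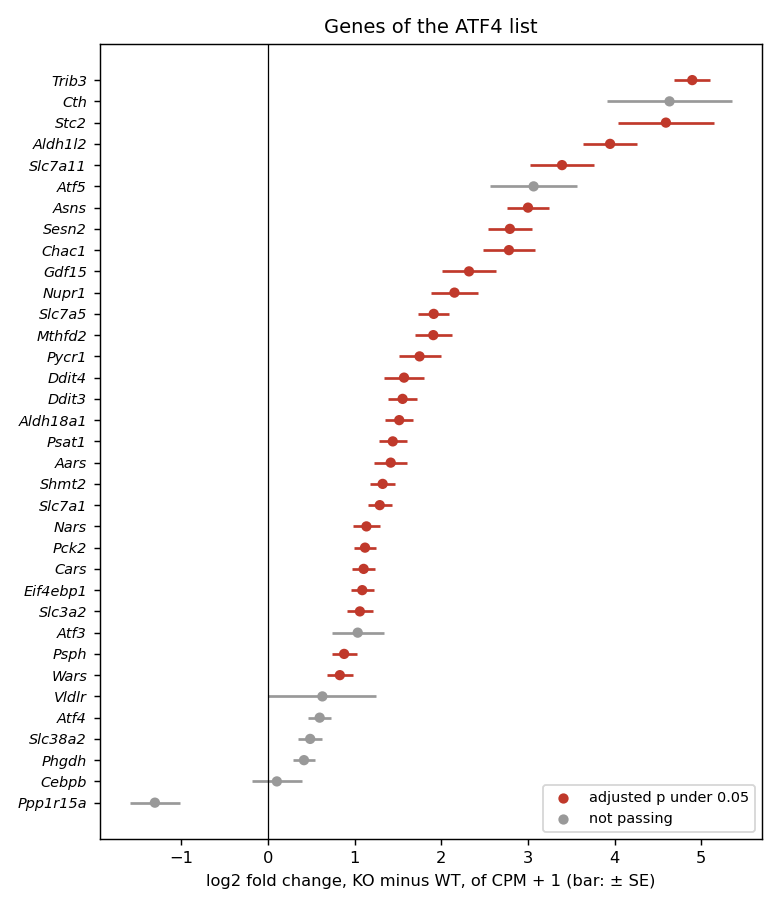
Log2 fold changes, knockout over wild type, of the measured genes in the ATF4 list, each point a gene and each bar its standard error from the limma fit. Of the 35 genes, 26 pass the test and all of those lie above 0.

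Mitochondrial genes moved in more than 1 direction. Chaperones and proteases of the mitochondrial unfolded protein response rose as a group: 2 of 16 genes passed over all genes and 6 adjusted over the list alone, all higher. Hspa9, the matrix chaperone mortalin, rose from 524 ± 8.26 to 994 ± 26.2 CPM (adjusted p = 0.0172), and Lonp1 is the other. The list's median log2 fold change was 0.36 with a camera adjusted p = 0.000121, against an adjusted p = 0.544 with an estimated correlation; 8 genes rose with a replicate block. Dnaja3 and Tomm40, with log2 fold changes of 0.72 and 0.45, passed limma with that block but not without it.

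RNAs encoded by mitochondrial DNA were lower, with a median log2 fold change of -0.49 over 13 genes (camera adjusted p = 0.0396, against an adjusted p = 0.678 with an estimated correlation). Of these, mt-Nd6, a complex I subunit gene, fell from 724 ± 183 to 336 ± 56.3 CPM (adjusted p = 0.0442 by limma and 0.0596 by edgeR), 0 rose, and 4 fell adjusted over the list alone. With a replicate block 5 fell. mt-Nd5, mt-Nd2 and mt-Nd1 had log2 fold changes of -0.77, -0.59 and -0.54 and did not pass; mt-Nd5 and mt-Nd1 did with the block. Mitochondrially encoded genes took 3.64% and 4.20% of reads in the wild-type libraries and 3.07% and 2.34% in the knockout libraries. The call was lost without wild-type replicate 1 (median -0.11, adjusted p = 0.126) and without knockout replicate 2 (median -0.26, adjusted p = 0.293).

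Nuclear genes of complex I, the entry point of the respiratory chain, were lower by a small amount, with a median log2 fold change of -0.19 over 35 genes (camera adjusted p = 0.0206, against an adjusted p = 0.729 with an estimated correlation). By limma 0 of them passed over all genes and 0 adjusted over the list alone, as 0 did by edgeR and with a replicate block, with 7 lower at an unadjusted p under 0.05. Ndufa1, Ndufa2, Ndufb7 and Ndufb3 had the smallest p, with log2 fold changes of -0.45, -0.44, -0.47 and -0.45. The call was lost without wild-type replicate 1 (median -0.14, adjusted p = 0.118) and without knockout replicate 2 (median -0.03, adjusted p = 0.329). Nuclear genes of complexes II to V missed the threshold (median -0.14, camera adjusted p = 0.0540) and passed it with a replicate block (adjusted p = 0.0483). Idh2, the mitochondrial NADP-dependent isocitrate dehydrogenase, fell from 313 ± 15.1 to 167 ± 35.9 CPM (adjusted p = 0.0406 by limma, 0.0582 by edgeR), while the list of the TCA cycle was not called (adjusted p = 0.105). Hk1, the first enzyme of glycolysis, rose from 232 ± 14.8 to 468 ± 105 CPM (adjusted p = 0.0343), and the glycolysis list was not called (adjusted p = 0.920). Adjusted over the list alone, 3 glycolysis genes rose and 2 fell, 1 TCA cycle gene fell and 0 genes of complexes II to V passed, of which 8 had an unadjusted p under 0.05 and 0 passed by edgeR. With a replicate block 3 glycolysis genes rose and 1 fell, 3 TCA cycle genes rose and 1 fell, and 1 gene of complexes II to V rose and 2 fell.

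Targets of p53 rose: 9 of 24 genes were higher and 0 lower, or 13 higher and 1 lower adjusted over the list alone. Zmat3, an RNA-binding tumour suppressor, rose from 4.38 ± 0.187 to 28.5 ± 7.05 CPM, Cdkn1a, an inhibitor of the cell cycle, from 18.0 ± 0.0689 to 44.2 ± 8.06 CPM, and the stress cytokine Gdf15 from 0.952 ± 0.255 to 8.71 ± 0.648 CPM. The median log2 fold change was 0.81 (camera adjusted p = 2.47e-06, against an adjusted p = 0.396 with an estimated correlation). The list shares 2 genes with the ATF4 list; without them 7 of 22 rose and the median was 0.62. The list of regulators of apoptosis was not called (adjusted p = 0.736), though the pro-apoptotic gene Bbc3 rose to a ratio of 2.30; 2 genes rose over all genes, adjusted over the list alone 2 rose and 1 fell, and with a replicate block 3 rose and 3 fell.

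Genes of the NRF2 antioxidant and glutathione list were higher, with a median log2 fold change of 0.23 over 22 genes (camera adjusted p = 0.0337, against an adjusted p = 0.544 with an estimated correlation). Slc7a11 and Gclm, a subunit of the enzyme that starts glutathione synthesis, rose over all genes; adjusted over the list alone, 6 rose and 3 fell, and with a replicate block 5 rose and 1 fell. Slc7a11 is also in the ATF4 list. Without it 1 of 21 genes rose, the median was 0.18 and the unadjusted camera p was 0.0433, against 0.0131 with it. The list of complexes II to V had a smaller unadjusted camera p, 0.0240, and missed the adjusted threshold. Without Slc7a11 the NRF2 list would therefore miss it too. Gclm went from 102 ± 7.83 to 200.2 ± 37.7 CPM. Srxn1 and Nqo1 had log2 fold changes of 1.08 and 1.12 and passed limma with the block but not without it. The call was lost without wild-type replicate 1 (adjusted p = 0.146) and without knockout replicate 1 (adjusted p = 0.0581).

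The type I interferon response rose. Of 41 measured genes 9 were higher and 0 lower; adjusted over the list alone, 29 were higher and 1 lower, and with a replicate block 24 and 1. The antiviral genes Oas3, Oasl1, Ifi44 and Isg15 rose to ratios of 2.79, 4.03, 3.83 and 3.87; Isg15, a ubiquitin-like protein, went from 7.14 ± 1.14 to 27.7 ± 4.46 CPM. The median log2 fold change was 0.68 (camera adjusted p = 3.54e-11, against an adjusted p = 0.396 with an estimated correlation). The NF-kB and inflammation list was not called (adjusted p = 0.967): the chemokine Ccl3 fell to a ratio of 0.195, Tnfaip2 rose to 2.71 (adjusted p = 0.0427 by limma and 0.0561 by edgeR), and Ccl4 and Tnf, with log2 fold changes of -1.69 and -1.17, passed limma with a replicate block but not without it. Adjusted over the list alone 1 rose and 3 fell, as with that block.

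Among lineage programmes, erythroid priming genes rose. Of 23 measured genes 10 were higher and 0 lower, or 16 higher and 1 lower adjusted over the list alone. Epor, the erythropoietin receptor, rose from 30.6 ± 1.72 to 81.7 ± 13.95 CPM and Ermap, an erythroid membrane protein, from 98.3 ± 5.91 to 271 ± 74.2 CPM, while Sphk1 and Samd14 reached ratios of 2.75 and 2.85. The transcription factors Gata1 and Klf1, chosen after their values were seen, rose to ratios of 2.20 and 2.54. The median log2 fold change was 0.93 (camera adjusted p = 3.92e-10, against an adjusted p = 0.678 with an estimated correlation). Globin genes took 0.0136% and 0.0137% of reads in wild-type and 0.0131% and 0.0159% in knockout libraries. The megakaryocyte and platelet list was not called (adjusted p = 0.284), and 1 of its genes, the thrombin receptor F2r, rose from 55.1 ± 10.5 to 110.0 ± 10.2 CPM; adjusted over the list alone, as with a replicate block, 2 rose and 1 fell.

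Genes of multipotent progenitors marked by CD48, CD34 and FLT3 fell: all 13 had negative log2 fold changes, with a median of -0.78 (camera adjusted p = 8.78e-07, against an adjusted p = 0.396 with an estimated correlation). Over all genes 0 rose and 2 fell, among them Cd48 (105 ± 14.7 to 60.6 ± 0.424 CPM, adjusted p = 0.0453 by limma and 0.0535 by edgeR). Adjusted over the list alone 4 fell, and with a replicate block 7 did. Flt3 and Cd34, chosen after their values were seen, did not pass without a block (log2 fold changes -1.19 and -1.23), and with one their adjusted p-values were 0.00129 and 0.000931.

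Lymphoid priming genes had a median log2 fold change of -1.14 over 23 genes (camera adjusted p = 0.000509, against an adjusted p = 0.678 with an estimated correlation). Ly6d fell from 60.5 ± 11.2 to 16.1 ± 3.65 CPM and the receptor Notch1 from 52.6 ± 7.82 to 22.4 ± 0.723 CPM; 0 rose, 3 fell adjusted over the list alone, and 4 fell with a replicate block. Without knockout replicate 1 the median was -0.06 and the call was lost (adjusted p = 0.239); without wild-type replicate 2 the median was -0.58. Mature B cell genes had a median of -1.10 over 11 genes (camera adjusted p = 0.0337, against an adjusted p = 0.701 with an estimated correlation), but 0 passed by limma over all genes, 0 adjusted over the list alone and 0 by edgeR. At an unadjusted p under 0.05 there was 1, and 5 fell with a replicate block. Cd79a, chosen after its values were seen, stood at 47.9 and 137 CPM in wild-type replicates 1 and 2 and at 15.8 and 81.4 CPM in knockout replicates 1 and 2. The B cell call was lost without wild-type replicate 2 (median -0.40, adjusted p = 0.575) and without knockout replicate 1 (median -0.26, adjusted p = 0.517).

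Granulocyte and monocyte priming genes had a median log2 fold change of -0.73 over 24 genes (camera adjusted p = 3.04e-06, against an adjusted p = 0.682 with an estimated correlation). Klf4 and Csf1r, the receptor of macrophage colony-stimulating factor, fell; Csf1r went from 69.5 ± 23.5 to 21.8 ± 5.47 CPM (adjusted p = 0.0404, 0.0545 by edgeR and 0.0862 with a replicate block). Over all genes 0 rose, adjusted over the list alone 7 fell, and with a replicate block 4 did. Wild-type replicate 2 stood apart for granule genes: Mpo, myeloperoxidase, was at 1877 and 5840 CPM in wild-type and at 1822 and 1355 CPM in knockout libraries, and Elane at 447 and 2048 CPM against 630.1 and 396 CPM, both chosen after their values were seen. Without that library the list's median was -0.04 and its adjusted p = 0.168; without wild-type replicate 1 the median was -1.44.

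Macrophage and dendritic cell genes had a median log2 fold change of 1.86 over 18 genes (camera adjusted p = 0.000179, against an adjusted p = 0.678 with an estimated correlation), yet members went both ways, and without wild-type replicate 1 the median was 1.01. Xcr1, a chemokine receptor of cross-presenting dendritic cells, rose from 8.35 ± 3.88 to 70.1 ± 10.1 CPM. The MHC class II genes H2-Eb1 and H2-Ab1 rose to ratios of 4.59 and 3.67, the latter with an adjusted p = 0.0441 by limma, 0.0531 by edgeR and 0.0506 with a replicate block. Siglech fell, making 3 higher and 1 lower, or 6 higher and 1 lower adjusted over the list alone; with a replicate block 3 were higher and 2 lower. The complement gene C1qa, chosen after its values were seen, stood at 1.30 and 15.5 CPM in wild-type and at 54.1 and 15.5 CPM in knockout libraries. Mast cell, basophil and eosinophil genes were not called (adjusted p = 0.712); the mast cell chymase Cma1 rose from 1.22 ± 0.451 to 11.2 ± 5.50 CPM, also the 1 gene called when adjusted over the list alone; with a replicate block 2 rose.

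Immediate-early genes, which cells induce within minutes of a stimulus or of dissociation, fell. Of 21 measured genes 0 rose and 7 fell, or 1 rose and 11 fell adjusted over the list alone; with a replicate block 1 rose and 10 fell. Fos fell from 293 ± 119 to 45.1 ± 3.6 CPM, Jun from 414 ± 162 to 62.2 ± 10.4 CPM, Zfp36, which destabilizes cytokine RNA, from 154 ± 44.5 to 36.1 ± 1.25 CPM, and Klf2 from 61.8 ± 6.74 to 19.8 ± 1.11 CPM. The median log2 fold change was -1.59 (camera adjusted p = 1.78e-08, against an adjusted p = 0.461 with an estimated correlation), and -0.82 without knockout replicate 2. The list of quiescence genes and CDK inhibitors was lower as a group, with a median of -0.40 over 16 genes (camera adjusted p = 0.00506, against an adjusted p = 0.461 with an estimated correlation), although its 1 called gene, Cdkn1a, rose; adjusted over the list alone 1 rose and 0 fell, and with a replicate block 1 rose and 2 fell. Egr1, Cdkn2c and Cdkn2d, with log2 fold changes of -2.07, -0.56 and -0.57, did not pass, though Cdkn2c and Cdkn2d did with the block.

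The other lists were not called, which does not show that they were alike. Long-term stem cell genes had a median log2 fold change of -0.11 (adjusted p = 0.967), with 1 gene higher, the stress-induced Nupr1, from 5.09 ± 0.239 to 26.5 ± 7.15 CPM, and 2 higher adjusted over the list alone; with a replicate block 5 were higher and 5 lower. Mitophagy and mitochondrial dynamics (adjusted p = 0.524) held 1 gene that rose, the autophagy receptor Optn, from 19.5 ± 1.23 to 65.6 ± 15.1 CPM, with 2 adjusted over the list alone and 2 with a replicate block. Endothelial and stromal genes (adjusted p = 0.141) held 1 that fell, Pecam1, from 114 ± 5.17 to 60.6 ± 6.90 CPM, with the same count adjusted over the list alone and 3 with a replicate block. For 9 further lists 0 genes passed by limma and 0 by edgeR; each is given with its camera adjusted p, its genes at an unadjusted p under 0.05 and its genes called with a replicate block. S phase genes had 0.967, with 3 and 1, and G2 and M phase genes 0.972, with 5 and 6. The mitochondrial ribosome had 0.706, with 13 and 4, and cytosolic ribosomal proteins 0.512, with 0 and 6. Fatty acid oxidation had 0.706, with 5 and 2, and cholesterol synthesis 0.507, with 2 and 0. Mitochondrial DNA maintenance had 0.284, with 2 and 1. Among other cell types, T and NK cell genes had 0.967, with 1 and 1, and neutrophil genes 0.712, with 1 and 0. The median and mean log2 fold change differed in sign for T and NK cell genes (-0.08 and 0.14), apoptosis genes (-0.01 and 0.11), NF-kB genes (0.19 and -0.00285) and S phase genes (-0.01 and 0.01), none of them called.

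Of the 36 lists 15 were called, 7 higher and 8 lower, and 16 with a replicate block. Camera with an estimated correlation called 0; fry called 4, those for ATF4, p53, interferon and quiescence, at an adjusted p = 0.0441. The call held in each of the 4 leave-one-out fits for 9 of the 15. Of 871 genes in the lists, 83 were called, 64 higher and 19 lower, with 201 by limma with a replicate block, 19 without knockout replicate 1 and 0 without knockout replicate 2.

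**Figure D3:**
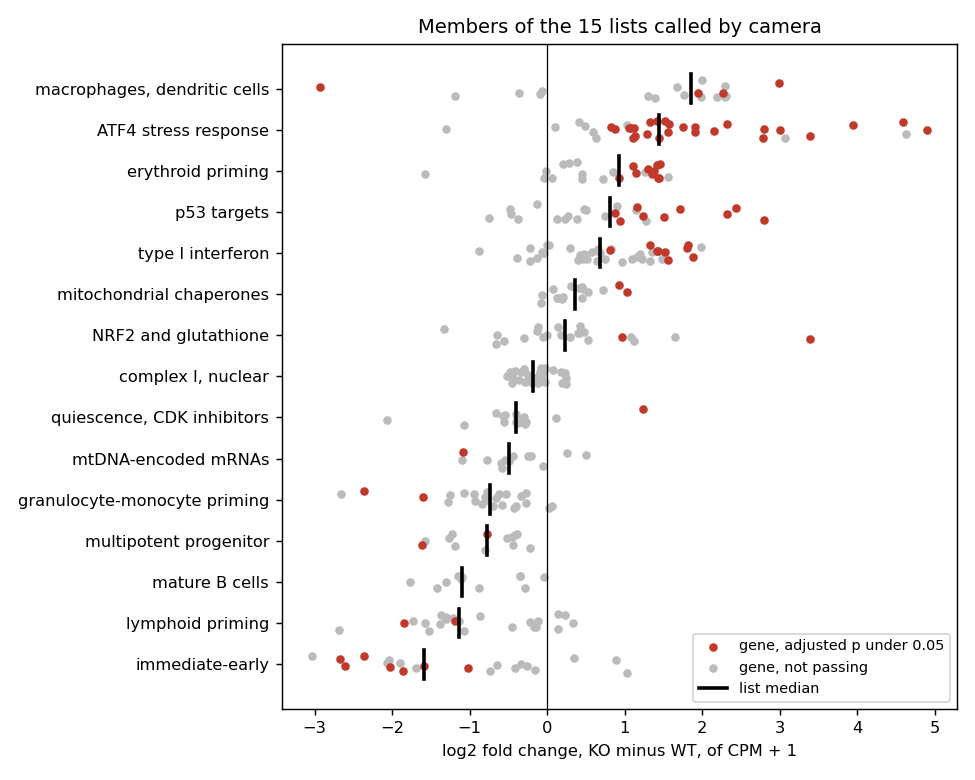
Log2 fold changes, knockout over wild type, of the members of the 15 lists called by camera with the preset correlation; each point is a gene, red where it passed over all genes, and each black bar is the list's median. The ATF4 list has a median of 1.44 and the immediate-early list a median of -1.59, and members of several lists lie on both sides of 0.

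The authors' deposited lists at a minimum log2 fold change of 0.5 hold 921 higher and 834 lower genes. They contained 240 of the 241 genes called higher here and 128 of the 128 called lower. Their lists at a minimum of 1, of 454 and 501 genes, contained 202 and 99. With a replicate block, 838 of 1013 higher and 663 of 766 lower genes were in the lists at 0.5. Because these lists were drawn from the same libraries, the overlap is not independent evidence of a direction. Log2 fold changes of the limma fit and the deposited table had a Pearson correlation of 0.909 and a Spearman correlation of 0.986 across genes, which are not independent replicates. Without knockout replicate 1 the overlap was 59 genes, without knockout replicate 2 it was 0 and without wild-type replicate 2 it was 903, against 368 with all libraries.

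In the authors' enrichment tables for the lists at 0.5, response to virus held 52 of the higher genes at a fold enrichment of 2.51 (authors' FDR 1.71e-06). The p53 signalling pathway held 15 at 2.89 and the folate carbon pool 8 at 5.57, both at an FDR of 0.0362. Among the lower genes, immune system process held 215 at a fold enrichment of 1.70 (FDR 9.79e-14) and haematopoietic cell lineage 14 at 3.45 (FDR 0.0233). B cell receptor signalling held 32 lower genes at a fold enrichment of 3.91. Of the terms listed, 245 of 1210 for higher genes and 153 of 781 for lower genes had an FDR under 0.05.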

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

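Limma with a replicate block and the refit of the authors' test were chosen after seeing the data. EdgeR without a block, the test planned for raw counts, was also added then, on recovered reads, and called 287 genes. The other alternatives were planned. The count of 369 genes became 1789 with edgeR and a replicate block, 1779 with limma and a block, 1756 with the authors' test, 1214 with DESeq2 and 117 with limma-voom, and ranged from 0 to 1068 with a library left out. The 0, without knockout replicate 2, is by limma, with 1209 genes at an unadjusted p under 0.05 and 3 called by edgeR. The count of called genes within the lists (83) became 197, 201, 181, 158 and 40 in the same order of fits, with a range of 0 to 151. The overlap with the authors' lists (368) became 1444, 1501, 1755, 1139 and 117, with a range of 0 to 903. The cause was not tested. The log2 fold change of Afg3l2 ranged from -1.43 to -1.15 with a library left out, and its call was lost without knockout replicate 1 and without knockout replicate 2. The number of lists called (15) became 0 with an estimated correlation and 4 with fry. In a simulation of independent genes, the version with an estimated correlation missed a true shift of 1 on the log2 scale. That does not show that the preset correlation holds where the genes of a list move together.

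For 3 lists not called with all libraries, leaving out 1 reversed the direction and gave a call. Long-term stem cell genes had a median of 0.11 without wild-type replicate 1, mast cell, basophil and eosinophil genes -0.44 without the same library, and mature neutrophil genes 1.35 without wild-type replicate 2. Over the 4 such fits the medians ranged from -0.38 to 0.11, -0.44 to 0.72 and -1.25 to 1.35; the cause was not tested. For 109 named genes under 9 alternatives with all libraries, 811 of 981 values kept direction and side of the threshold, 48 lost the call, 122 gained it and 0 changed direction. With 1 library left out, 305 of 436 were unchanged, 105 lost the call and 26 gained it. For the lists by camera with the preset correlation, 178 of 180 values were unchanged under 5 alternatives with all libraries. This leaves out the estimated correlation and fry, which ended most calls. The limma and edgeR alternatives with a replicate block put the same log2 values and design into camera. Their list results are therefore identical and not separate tests. With 1 library left out, 123 of 144 were unchanged, 10 lost the call, 8 gained it and 3 reversed. The 8 were cytosolic ribosomal proteins (without wild-type replicate 2, adjusted p = 0.00364, and without knockout replicate 1, 0.0210), T and NK cells (without wild-type replicate 2, 0.0379), complexes II to V (without knockout replicate 1, 0.00821), endothelial and stromal genes (without knockout replicate 2, 0.0105), stem cell and mast cell genes (without wild-type replicate 2, 0.00633 and 0.0198) and neutrophil genes (without wild-type replicate 1, 1.7e-14). No filter at all was not run, because all 15255 deposited genes pass the planned filter. Depth ranged from 16522338 to 17271936 reads per library; on simulated libraries of this design, limma recovered 37% of genes changed 2-fold.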

Other observations

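All tests in this part were chosen after the results were seen, as were its gene lists other than the erythroid, the immediate-early and the CD48, CD34 and FLT3 list. Of 20 cytosolic aminoacyl-tRNA synthetase genes, which charge tRNAs with amino acids, 11 rose and 0 fell, with a median log2 fold change of 0.90 (adjusted p = 0.276 with an estimated correlation). The ATF4 list holds 4 of these genes; of the other 16, 7 rose, with a median of 0.65. Gars, Eprs and Sars rose to ratios of 2.57, 2.53 and 2.18. Of 17 mitochondrial synthetase genes 0 passed by limma, 5 had an unadjusted p under 0.05 and 2 passed with a replicate block (median 0.26, adjusted p = 0.276 with an estimated correlation); the difference between both sets was not tested. Genes of antibody-secreting cells were lower, with 4 of 22 called and 10 with a replicate block (median -0.83, adjusted p = 0.276 with an estimated correlation). Without wild-type replicate 2 the median was -0.49 and 8 of the 22 were above 0. Immunoglobulin and Jchain reads made up 2.03% and 3.14% of wild-type and 1.40% and 1.87% of knockout libraries.

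Within 10 Mb of Afg3l2, 7 of 102 other genes were called (6.86%), against 351 of 14849 on other chromosomes (2.36%; Fisher's exact test, two-sided p = 0.0113) and 9 of 274 on the rest of the chromosome (3.28%). With a replicate block the counts were 17 of 102 (16.7%) and 1732 of 14849 (11.7%), and the same exact test gave p = 0.122, so the excess no longer passed. Spire1, which lies nearby on chromosome 18 from 67488209 to 67610790, rose with a log2 fold change of 1.81 (limma adjusted p = 0.0119). Neighbouring genes are not independent of each other, and the strain background of the mice is not in the labels.

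Erythroid priming genes rose in the knockout, with 10 of 23 called and a camera adjusted p = 0.678 with an estimated correlation. Carry-over of haemoglobin-making cells is argued against by the 6 globin and late erythroid genes, all of them in the erythroid list, whose median log2 fold change was 0.14 (SD over genes 0.19) against 1.27 for the other 17 members. A larger share of erythroid-primed progenitors may contribute, since the CD48, CD34 and FLT3 list had a median of -0.78. That value would also fit a change within each cell, so the explanations cannot be told apart in bulk RNA. A direct effect of the genotype stays open.

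Of 21 immediate-early genes 7 were called lower and 0 higher, and 3 of the 21 had log2 fold changes above 0. The camera adjusted p of the list was 0.461 with an estimated correlation. A single deviating library as the whole cause is argued against by the list's medians with a library left out. The one nearest 0 was -0.82, without knockout replicate 2, against -1.59 with all. A difference in handling before lysis could act on the same genes. Heat-shock genes outside the list had a median of 0.12 (SD over genes 0.35), with 10 of 14 above 0, and since they went both ways the effects of handling and genotype cannot be told apart.

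Genes of XCR1-positive dendritic cells (cDC1) were higher, with 10 of 18 called and a median log2 fold change of 1.69, while 7 of 16 plasmacytoid and 6 of 17 cDC2 and monocyte genes were lower (medians -1.12 and -1.33; adjusted p = 0.276 with an estimated correlation for each list). The lists fixed in advance already hold 2, 5 and 4 of these genes, and without wild-type replicate 2 the medians were 2.05, -0.89 and -0.71. Carry-over of all 3 cell types alike would raise the genes of all 3 lists. The medians of the cDC1 and the cDC2 and monocyte genes instead differed by 3.02. Their interquartile ranges, 1.27 to 2.38 and -2.04 to -0.69, did not meet. Because these lists were written after the values were seen, the difference restates the pattern and is no separate test of that explanation. Carry-over of cDC1 cells alone, which would also be a loss of purity, is a candidate explanation: 4 abundant MHC class II genes had a median of 1.96 (SD over genes 0.21), as such cells would bring. All 4 were in the lists fixed in advance, and H2-Eb1 and H2-Ab1 had already been seen to rise, so their median is no separate support. Cd74 and H2-Aa did not pass limma (adjusted p = 0.0885 and 0.0699), though H2-Aa did with a replicate block (adjusted p = 0.0374). The lineage-negative, c-Kit-positive gate should remove cDC1 cells, and Irf8 and Itgax, also made by these cells, had log2 fold changes of -0.54 and -0.07. Irf8 was the only cDC1 list member not above 0, with 17 of 18 above. Irf8 stood at 339 and 557 CPM in the wild-type libraries and at 293 and 306 CPM in the knockout libraries, and did not pass (limma adjusted p = 0.256). The size of an admixture was not estimated, so the values of Irf8 and Itgax do not decide the question. A change of the programme within gated progenitors stays open as a hypothesis.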
